A study of Mus musculus with 16 samples.

How the data were processed

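Mouse embryonic stem cells were profiled by sequencing of total RNA and of small RNA. Total RNA came from wild-type and Dgcr8 knockout cells, each in 2iL (medium with MEK and GSK3 inhibitors plus LIF) and at 48 h of differentiation. Small RNA came from wild-type cells at 0, 12, 24 and 48 h after leaving 2iL. Each of the 8 groups held 2 libraries (16 in all), which the study design calls biological replicates; what was repeated (culture, passage or day) was not given in the sources used here. The column names label the wild-type cells v65 and the titles label the Dgcr8 knockout cells ES1, so there was 1 line per genotype. The titles describe the differentiation medium as N2B27 with bFGF and KSR. No knockout small RNA was analysed here.

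For the total RNA, the authors deposited gene-level FPKM values, and the submitters' processing notes name STAR 2.5.0 for alignment, Cufflinks 2.2.1 for quantification and mm10 as the genome build. The table held 41258 entries with 41202 Ensembl identifiers, of which 40071 were matched to a gene symbol and 1131 were not. The 56 repeated identifiers and 8 symbols shared by several identifiers were never joined into one value. Read numbers per total RNA library were not available, so the sequencing depth of these libraries is unknown; the FPKM values summed to 475199 to 548394 per library, and 11410 to 12024 genes reached 1 FPKM. The 2 libraries of a group were correlated at 0.978 to 0.984 on the log2 scale. The median standard error of a log2 difference was 0.0882, and 0.125 for a difference between 2 differences.

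For the small RNA, the authors deposited a relative signal per hairpin and arm, for 1696 arms, of which 1550 were above 0 in at least 1 library. How small RNA reads were trimmed and matched to hairpins and arms was not given in the sources used here. Every library summed to 110000. The steps between low values fit a sum of 2 read tables per library, each scaled to a total of 55000. Solving for these totals returned whole reads within a tolerance of 0.01 reads for 100% of the 610 to 651 values per library that lay below 100 reads. The solution gave 5441382 to 9131989 reads and 1171 to 1268 arms above 0 per library. One recovered read was worth 0.0121 to 0.0202 on the deposited scale. Replicate libraries were correlated at 0.995 to 0.997. Floors given for a count of 0 correspond to 3 reads and cover counting error only, not differences between cultures.

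The comparisons, the gene lists, the miRNA families, the thresholds, the rule for naming genes and most alternatives were fixed before the data were examined. For total RNA, log2(FPKM + 1) was fitted with limma 3.58.1 (linear model with 4 group means, moderated t with an intensity trend) for the 13166 genes with at least 1 FPKM in at least 2 of the 8 libraries. The residual degrees of freedom were 4 and the prior degrees of freedom 3.12. A gene was called changed when its Benjamini-Hochberg adjusted p over all tested genes was below 0.05. The plan allowed for either FPKM or read counts, and the FPKM branch was used. The 5 comparisons were 48 h against 2iL in wild-type cells, the same in Dgcr8 knockout cells, knockout against wild type in 2iL, knockout against wild type at 48 h, and the difference between the 48 h changes of the 2 genotypes (the interaction). With 2 libraries against 2, 33.3% of genes without any difference have groups that do not overlap. Replicate numbers were not taken to pair libraries across groups.

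The 24 gene lists were naive pluripotency, general pluripotency, formative and primed pluripotency, MEK/ERK response, WNT/beta-catenin response, LIF/STAT3 response, NODAL/TGF-beta response, PI3K/AKT components, miRNA pathway, miRNA host transcripts, reported miR-290 and miR-302 targets, G1/S regulators, p53 response, glycolysis, DNA methylation machinery, germline genes, imprinted genes, housekeeping genes, and markers of primitive endoderm, primitive streak and mesoderm, neuroectoderm, trophectoderm, the 2-cell-like state, and fibroblasts and feeder cells. They were written from general knowledge of this field. Some lists share genes, so their results are not independent. Klf4, Klf5, Tfcp2l1 and Gbx2 are in both the naive and the LIF/STAT3 list. Cdkn1a, Lats2 and Rbl2 are in both the target and the G1/S list. Cdkn1a and Ei24 of the targets are also in the p53 list. Further genes are shared by other lists, such as Akt1, Dppa3 and Tet2. Counts are given out of the members that passed the expression filter, such as 4 of 10 for fibroblasts and feeder cells, 3 of 9 for primitive streak and mesoderm (T, Mixl1 and Mesp1 did not pass) and 5 of 10 for the 2-cell-like state. Each list with at least 3 measured members was tested with camera in limma with a preset correlation of 0.01 between genes, adjusted over the 24 lists. Camera was repeated with the correlation estimated from the data, since the preset value makes only a small, fixed allowance for members that vary together. Counts given as adjusted over the list alone used the members' own p-values adjusted among themselves.

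For small RNA, log2 of the signal plus 0.01195 (the smallest value above 0) was fitted with limma for the 1415 hairpin arms above that value in at least 2 libraries (1258 distinct mature arms), with contrasts of 12, 24 and 48 h against 0 h and a moderated F test over the course. The 17 families, 51 tests over the 3 contrasts, were tested with camera and adjusted together. They were miR-290, miR-302, miR-17, miR-106a, miR-106b, let-7, miR-200, miR-15 and miR-16, miR-130 and miR-301, miR-182, miR-34, miR-181, the neural, muscle, and mesenchymal and feeder miRNAs, and the miRNAs of the Dlk1–Dio3 and Sfmbt2 loci. Copies of 1 mature arm from several hairpins are listed as separate arms. Since whole reads were recovered, edgeR 4.0.16 (quasi-likelihood F test, TMM factors of 0.949 to 1.07, filterByExpr, 896 arms) was added after the data were seen. Shares of a family are percentages of the summed signal of all arms.

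Genes were named by a fixed rule. For each total RNA comparison these were the 6 largest rises and 6 largest falls among called genes whose groups did not overlap, leaving out unnamed gene models and repeated symbols; 18 genes were always named (Dgcr8, Akt1, Nanog, Pou5f1, Sox2, Klf4, Esrrb, Zfp42, Tfcp2l1, Prdm14, Fgf5, Otx2, Dnmt3b, Pou3f1, Cdkn1a, Lats2, Rbl2 and Casp2). For each list the rule added the called members with the largest rises and falls, 2 per direction, or the members with the highest mean if none was called. Not every gene that the rule picked is named in the text. For the interaction the genotypes also had to be separate in 2iL or at 48 h. For each small RNA contrast it took the 5 largest rises and 5 largest falls and each family's most abundant member. Other members are named only where their list is described, as the few exceptions to its direction, and these were picked after their values were seen.

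The fits were tested on simulated data drawn around the measured means and spreads, as normal log2 values for total RNA and negative binomial reads for small RNA. For total RNA, 50 well-expressed genes per effect size were changed. A log2 difference of 0.5 was called for 82% of genes in the wild-type comparison and 38% in the interaction, a difference of 1 for 100% and 96%, and 6 to 8 of 12966 unchanged genes were called. Few genes were changed in this simulation, whereas 42.9% to 71.8% of genes were called in the measured comparisons. Power and false calls under the Benjamini-Hochberg threshold depend on that share, so these figures do not carry over to the measured comparisons. For small RNA, a difference of 1 was called for 87.9% to 93.9% of arms by limma and 90.9% to 98.5% by edgeR. These small RNA figures hold only for changed arms below 0.05% of the reads. The simulation was changed after it had failed 3 times, when changed arms could be of any abundance. In that form the changed arms took 24.9%, 26.6% and 39.3% of the reads at 12, 24 and 48 h. The limma fit then called 26 of 1189, 2 of 1200 and 137 of 1198 unchanged arms, and edgeR called 7 of 698, 11 of 686 and 9 of 686. Changes in a few abundant miRNAs can therefore shift the values of all others on this relative scale.

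Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, quantile and median-ratio scaling, an added fold threshold, fits without trend, with robust weights or with only the libraries compared, a term for the replicate number, leaving out each library in turn, camera with an estimated correlation, and for small RNA a pseudocount 10 times larger or smaller, other filters, scalings and shares. Fits without 1 library assume that the lone library left in its group varies like the other groups. Added after seeing the data were edgeR, merging of hairpin copies, median-ratio scaling for named genes, named miRNAs and families, and 3 further settings for miRNAs and families. Sites for miRNA seeds in 3′ untranslated regions were not analysed here, because no untranslated-region sequences were available. Versions were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.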

Results

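Gene expression was measured as FPKM in wild-type and Dgcr8 knockout mouse embryonic stem cells, in 2iL and at 48 h of differentiation, with 2 libraries per group. Small RNA was measured in wild-type cells only, at 0, 12, 24 and 48 h after leaving 2iL, also with 2 libraries per group and 5441382 to 9131989 recovered reads per library. The comparisons ask what changes when wild-type cells leave 2iL, what changes in cells without Dgcr8, how the genotypes differ in each condition, whether the change itself differs between genotypes, and which miRNAs change over the course in wild-type cells. Dgcr8 encodes the RNA-binding partner of Drosha, which releases most miRNA precursors from their transcripts. Replicates lay close together and the 4 total RNA groups were separate on the first 3 principal components, which held 55.9%, 25.4% and 10.8% of the variance.

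Dgcr8 itself was measured in every sample. The wild-type libraries held 18.3 and 19.2 FPKM in 2iL and 20.7 and 20.9 at 48 h; the knockout libraries held 9.11 and 9.33 in 2iL and 7.84 and 7.80 at 48 h. The log2 difference between genotypes was −0.95 (SE 0.05, limma adjusted p = 8.0e-06) in 2iL and −1.31 (adjusted p = 9.6e-07) at 48 h, so a transcript signal remained in the knockout. FPKM per gene cannot say which exons the reads come from, and an allele that lacks only part of the gene would leave such a signal. Within each genotype Dgcr8 moved little by 48 h, with a log2 change of 0.14 in wild-type cells (adjusted p = 0.049) and −0.21 in the knockout (adjusted p = 0.013). Neither of these small calls held when single libraries were left out: the wild-type adjusted p was 0.197 without 2iL replicate 1, and the knockout adjusted p was 0.061 without 48 h replicate 2. The genotypes also differ in cell line, with 1 line each, so every difference between them is a difference between lines as well.

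When wild-type cells left 2iL, most transcription factors of naive pluripotency fell steeply. Mean Nanog fell from 212 to 5.34 FPKM, Esrrb from 169 to 4.85, Tfcp2l1 from 64.5 to 0.802 and Klf4 from 34.2 to 0.462. The genes of the formative state rose at the same time: Pou3f1 from 0.764 to 55.3 FPKM, Otx2 from 3.51 to 26.8, Fgf5 from 0.12 to 4.86, and the de novo methyltransferases Dnmt3a from 29.2 to 274 and Dnmt3b from 102 to 553. Pou5f1, shared by both states, stayed high at 912 and 716 FPKM, whereas Sox2 fell from 130 to 30.7.

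**Figure D1:**
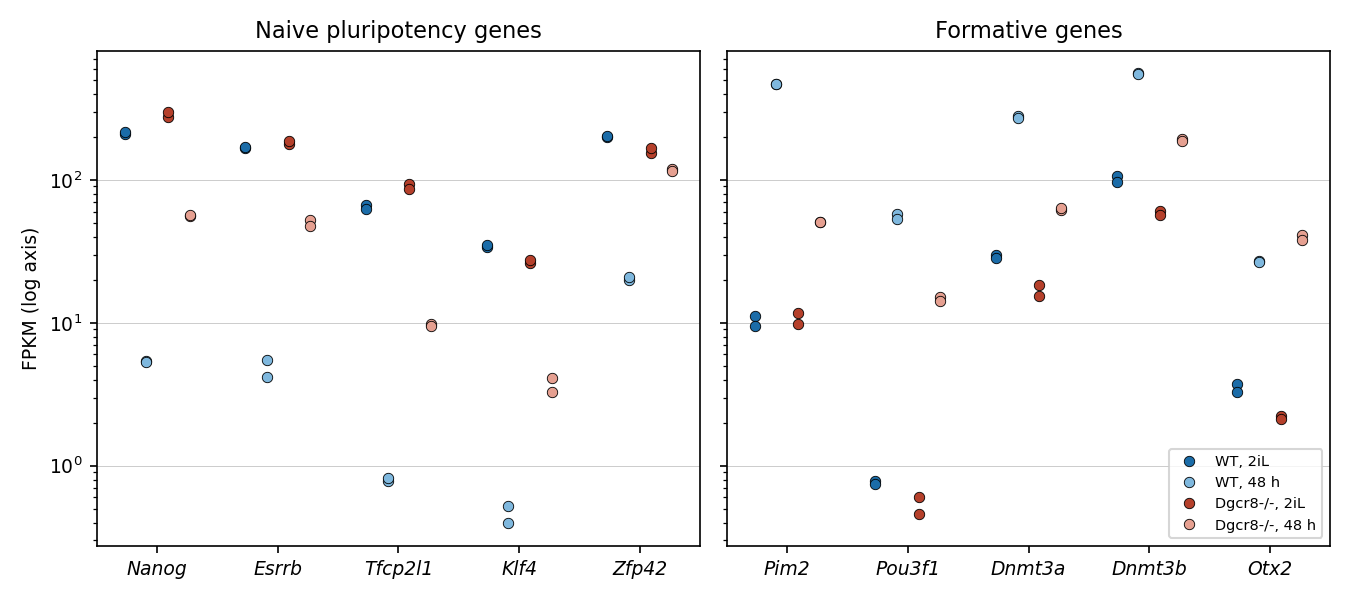
FPKM on a log axis in every library for 5 naive genes and 5 genes that rose in wild-type cells, with 1 point per library and colours for the 4 groups. Mean Nanog at 48 h was 5.34 FPKM in wild-type and 56.4 in knockout cells, and mean Pim2 was 467.3 and 50.8.

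Of 13166 genes tested with limma, 7439 changed by 48 h in wild-type cells (4073 rose, 3366 fell), and 1025 rises and 807 falls were at least 2-fold. Which direction prevailed depended on the setting, with 3754 rises and 3860 falls after median-ratio scaling and 2449 and 2534 among genes with a mean FPKM of at least 5. Among the largest rises were those of Pim2, a kinase of the STAT5 and STAT3 pathways (log2 5.37, SE 0.09, adjusted p = 5.6e-08), the membrane protein gene Tmem54 (5.10, SE 0.11, adjusted p = 1.2e-07), Pou3f1, Btbd17 (4.85) and the protocadherin Pcdh1 (4.62). Carbonic anhydrase Car4 was listed at 0 in both 2iL libraries and reached 40.1 and 36.9 FPKM. Among the largest falls were those of Tcl1, a cofactor of AKT (−5.21, SE 0.13, adjusted p = 1.7e-07), Tfcp2l1 (−5.18), the junction protein gene Jam2 (−5.10), Nanog (−5.07, SE 0.05, adjusted p = 2.2e-08) and the oocyte factor Khdc3 (−4.92).

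Among the fixed lists, 17 of 18 naive pluripotency genes fell and 1 rose (median log2 −3.23, camera in limma, adjusted p = 1.2e-12, and adjusted p = 0.0763 with an estimated correlation). The exception was the homeobox gene Gbx2 (0.50). In the formative and primed list 17 of 18 genes rose and Foxd3 was not called (median 2.19, adjusted p = 1.7e-09, and adjusted p = 0.136 with an estimated correlation). LIF/STAT3 response genes fell, 10 of 11, with Socs3 from 36.9 to 2.5 FPKM and Stat3 from 24.0 to 4.23 (median −2.26, camera adjusted p = 4.9e-06, and adjusted p = 0.0763 with an estimated correlation). MEK/ERK response genes rose, 11 of 16, led by the phosphatases Dusp4 (log2 4.11) and Dusp6 (2.37), while the ERK-induced factors Etv5 (−0.49) and Junb (−0.60) and the survival gene Ier3 (−0.38) fell (list median 0.60, camera adjusted p = 0.017, and adjusted p = 0.426 with an estimated correlation). The removal of the MEK inhibitor and of LIF is part of the design. Imprinted genes rose, 14 of 17, with falls of the growth-arrest factor Plagl1 (−1.73) and of Impact (−0.16), a translation regulator whose small call was lost under some settings (median 1.32, camera adjusted p = 3.1e-04, and adjusted p = 0.0961 with an estimated correlation). All 4 measured fibroblast and feeder genes of 10 listed rose, with Thy1 from 2.42 to 9.23 FPKM and Tagln from 0.396 to 9.20 (median 1.58, camera adjusted p = 0.0093, and adjusted p = 0.166 with an estimated correlation). Col1a1, Col1a2, Col3a1 and 3 others of that list stayed under the expression filter.

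No other list was called in wild-type cells, although many of their members changed. Glycolysis genes divided into 4 rises and 10 falls of 16, with the glucose transporter Slc2a1 up (log2 1.40) and Slc2a3 (−2.44) and Pfkp (−2.65) down (median −0.23, camera adjusted p = 0.071). NODAL/TGF-beta response genes gave 4 rises (5 when adjusted over the list alone) and 6 falls of 11, with Nodal at −2.11, Lefty2 at −3.47 and Skil at 1.81 (median −1.01, camera adjusted p = 0.411). For the WNT/beta-catenin response, 4 rose and 4 fell of 10, with Lef1 up (1.99) and Notum down (−4.77); the median was 0.11, the mean −0.59 and the camera adjusted p 0.943. General pluripotency gave 3 rises and 6 falls of 10 (median −0.35, adjusted p = 0.285), germline genes 4 and 2 of 7 (1.12; 0.431), and 2-cell-like genes 1 rise of 5, none when adjusted over the list alone (0.20; 0.712). The miRNA pathway gave 7 rises (8 when adjusted over the list alone) and 4 falls of 12 (median 0.17, adjusted p = 0.473), including a rise of Prkra (1.11) and a fall of Ago1 (−0.63), and miRNA host transcripts 6 and 2 of 9 (0.64; 0.265). Markers of other lineages were not called as groups: primitive endoderm had 3 rises and 1 fall of 4 (median 1.21, adjusted p = 0.315) and neuroectoderm 2 and 2 of 4 (0.06; 0.943). Trophectoderm had 2 and 1 of 4 (0.24; 0.943), and primitive streak and mesoderm 0 and 3 of 3 (−0.74; 0.071). Housekeeping genes gave 1 rise and 5 falls of 10 (−0.18; 0.161). G1/S regulators, p53 response, PI3K/AKT components, DNA methylation machinery and reported miR-290 and miR-302 targets had camera adjusted p-values of 0.298, 0.966, 0.943, 0.966 and 0.546.

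In Dgcr8 knockout cells most of the same naive genes fell too, but most of them kept more of their 2iL level than in wild-type cells. Nanog fell from 285 to 56.4 FPKM, Klf4 from 26.8 to 3.71 and Tfcp2l1 from 89.6 to 9.64, while Zfp42 fell only from 161 to 116, Nr0b1 from 83.5 to 67.7 and Klf2 from 238 to 186. Formative genes rose to lower levels than in wild-type cells: Pou3f1 reached 14.7 FPKM, Dnmt3b 189 and Fgf5 0.723. Otx2 rose from 2.16 to 39.6 FPKM and so ended above its wild-type level.

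By 48 h, 6368 genes changed in the knockout (3490 rose, 2878 fell), 677 rises and 533 falls of at least 2-fold. Falls prevailed instead after median-ratio scaling (3266 rises, 3383 falls) and without knockout 2iL replicate 1 (2852 and 2892). The largest rises were those of Dnmt3l, the cofactor of the de novo methyltransferases (log2 4.16, SE 0.07, limma adjusted p = 1.7e-07), the stress gene Gadd45g (4.06), the Notch ligand Dll1 (3.92), the lactate transporter Slc16a3 (3.86) and the proneural factor Neurod1 (3.79). Dcn, an extracellular matrix gene, rose from 0.0372 and 0 FPKM to 11.9 and 12.6. Among the largest falls were those of the homeobox gene Cdx1 (−4.57, SE 0.10, adjusted p = 3.2e-07), the channel gene Trpm1 (−4.43) and the WNT target Sp5 (−4.19). The histocompatibility gene H2-Bl (−3.97) and the small nucleolar RNA Snora7a (−3.57) also ranked high, but H2 paralogs share reads and FPKM of very short genes is uncertain.

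Of the naive list, 16 of 18 genes fell in the knockout, Gbx2 rose (0.72) and Pecam1 was not called (median −1.28, camera in limma, adjusted p = 5.9e-09, and adjusted p = 0.078 with an estimated correlation). Formative and primed genes gave 12 rises (13 when adjusted over the list alone) and 2 falls of 18, the falls being Tead2 (−0.38), a Hippo-pathway factor, and Foxd3 (−0.39), a repressor of alternative fates (median 1.36, camera adjusted p = 4.3e-05, and adjusted p = 0.215 with an estimated correlation). LIF/STAT3 genes fell, 10 of 11 (median −1.54, camera adjusted p = 3.3e-06, and adjusted p = 0.078 with an estimated correlation). MEK/ERK response genes rose, 12 of 16, apart from falls of Etv4 (−0.47) and Junb (−0.84) (0.66, adjusted p = 0.0044, and adjusted p = 0.251 with an estimated correlation). Imprinted genes rose, 12 of 17, with 4 falls led by Plagl1 at −2.98 (0.83, adjusted p = 0.0102, and adjusted p = 0.172 with an estimated correlation). So did the 4 measured fibroblast and feeder genes (1.22, adjusted p = 0.0060, and adjusted p = 0.172 with an estimated correlation).

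Further lists were called in the knockout but not in wild-type cells, which is no test of a difference: of these 7 lists, the interaction was called for the WNT/beta-catenin and 2-cell-like genes alone. WNT/beta-catenin response genes fell, 5 of 10, with Cdx1, Sp5 and Axin2 the clearest (20.4 to 1.73 FPKM for Axin2), and none rose, or 1 when adjusted over the list alone (median −0.24, camera adjusted p = 0.0162, and adjusted p = 0.313 with an estimated correlation). The 3 measured primitive streak and mesoderm markers of 9 listed fell, with Evx1 from 5.53 to 0.595 FPKM and Gsc from 4.22 to 0.178 (−2.03, adjusted p = 0.0064, and adjusted p = 0.172 with an estimated correlation), a call that ended with no expression filter. Of the measured 2-cell-like genes, 4 of 5 fell (5 when adjusted over the list alone), Zscan4f from 6.25 to 3.11 FPKM (−0.56, adjusted p = 0.0102, and adjusted p = 0.172 with an estimated correlation). The p53 response list gave 10 rises and 1 fall of 13; the fall was Cdkn1a, the cell-cycle inhibitor (−0.80; list median 0.43, camera adjusted p = 0.0070, and adjusted p = 0.340 with an estimated correlation). miRNA host transcripts gave 7 rises and 1 fall of 9, with Meg3 at 1.65 and Rian at 1.72 (1.02, adjusted p = 0.0083, and adjusted p = 0.277 with an estimated correlation). The DNA methylation list gave 7 rises and 1 fall of 11, the fall being the demethylase Tet2 at −0.89 (0.39, adjusted p = 0.0281, and adjusted p = 0.340 with an estimated correlation). Glycolysis gave 3 rises and 9 falls of 16 (−0.18, adjusted p = 0.0188, and adjusted p = 0.508 with an estimated correlation), a call that quantile scaling also ended. Among the uncalled lists, reported miR-290 and miR-302 targets gave 5 rises and 4 falls of 13 (−0.04; 0.768).

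The genotypes already differed in 2iL. Most of the reported targets of miR-290 and miR-302 were higher without Dgcr8: the cell-cycle inhibitor Cdkn1a at 250 against 64.7 FPKM, the Hippo kinase Lats2 at 6.32 against 1.07, the apoptotic protease Casp2 at 33.3 against 13.4 and the pocket protein Rbl2 at 6.08 against 2.71. Naive genes went both ways, with Nanog at 285 against 212 FPKM, Prdm14 higher (log2 1.03), Tcl1 lower (−0.83) and Esrrb not called (0.12). Lin28a, a repressor of let-7 maturation, was nearly absent from the knockout (1.10 against 105 FPKM), and Dnmt3l was low (10.9 against 123).

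In 2iL, 8345 genes differed (4032 higher and 4313 lower in the knockout), 996 higher and 583 lower by at least 2-fold. More genes were higher than lower after median-ratio scaling (4474 and 3976), without a filter (4471 and 4188) and without knockout 2iL replicate 1 (3809 and 3763). Lin28a (log2 −5.65, SE 0.07, limma adjusted p = 2.5e-08), the peptide hormone gene Calca (−4.93), the homeobox gene Rhox5 (−4.71, SE 0.05, adjusted p = 1.3e-08), the membrane-binding Anxa6 (−3.57) and the transglutaminase Tgm1 (−3.45) were among the most reduced. Higher genes included the large noncoding RNA Kis2 (5.30), the T-cell receptor components Cd3g (4.52) and Cd3d (4.30), the osteocalcin paralog Bglap3 (4.39), and Alox5ap, a gene of leukotriene synthesis (5.08), whose standard error of 0.73 was large. The short genes Mir8094 and Snora31 also qualified, but FPKM of such short genes is uncertain.

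The reported targets of miR-290 and miR-302 were 11 higher and 1 lower of 13 (median 1.17, camera in limma, adjusted p = 0.0018, and adjusted p = 0.191 with an estimated correlation). Cdkn1a (1.93, SE 0.04), Lats2 (1.83, SE 0.13), Irf2 (1.58), Ei24 (1.27) and Casp2 (1.26, SE 0.06) stood highest, and the NODAL antagonist Lefty2 was lower (−2.63). PI3K/AKT components were 13 higher (14 when adjusted over the list alone) and 2 lower of 17, with Pik3cb (1.20), Akt2 (1.15) and Akt1 (0.61) up and the mTOR-complex gene Rptor (−0.18) and its inhibitor Tsc2 (−0.26) down (median 0.63, adjusted p = 0.0018, and adjusted p = 0.191 with an estimated correlation). All 5 2-cell-like genes were higher, with Zscan4d at 5.95 against 0.553 FPKM (1.74, adjusted p = 0.0039, and adjusted p = 0.191 with an estimated correlation); Zscan4 paralogs share reads, so the members are not independent. G1/S regulators were 12 higher and 3 lower of 18, including a higher Ccnd2 (2.09) and Rb1 (1.21) and lower Ccne1 (−1.09) and Cdk2 (−0.45), which drive entry into S phase (0.40, adjusted p = 0.041, and adjusted p = 0.319 with an estimated correlation). Without wild-type 2iL replicate 1 the G1/S list was no longer called (adjusted p = 0.056).

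The p53 response list was 7 higher and 0 lower of 13 in 2iL, with Pmaip1 at 1.59 (median 0.59, camera in limma, adjusted p = 0.034, and adjusted p = 0.535 with an estimated correlation). WNT/beta-catenin response genes were 6 higher of 10, with Cdx1 at 29.7 against 3.45 FPKM and Notum at 229 against 50.9 (0.40, adjusted p = 0.035, and adjusted p = 0.535 with an estimated correlation), a call that ended with a pseudocount of 0.1. Glycolysis genes were 10 lower and 2 higher of 16, with Ldha at 136.3 against 529 FPKM and Aldoa at 439 against 934. The entry kinase Hk1 (0.27) and Pdk1 (0.39), which restrains pyruvate oxidation, were higher (−0.42, adjusted p = 0.021, and adjusted p = 0.535 with an estimated correlation); quantile scaling ended the list call. The 3 measured primitive streak and mesoderm markers were higher (1.39, adjusted p = 0.045, and adjusted p = 0.336 with an estimated correlation), but that call ended without wild-type 2iL replicate 1 (adjusted p = 0.056) or knockout 2iL replicate 1 (adjusted p = 0.064). It also ended with quantile or median-ratio scaling, a pseudocount of 0.1 or no expression filter. Naive pluripotency was 10 higher and 6 lower of 18 (0.40, adjusted p = 0.209), and formative genes 4 higher and 7 lower of 18 (−0.13; 0.474). Among miRNA host transcripts, Meg3, Rian and Mirg of the Dlk1–Dio3 locus were lower (log2 −3.09, −2.97 and −1.87) and Mir17hg (1.95) and Mir22hg (1.18) higher, so the list of 9 had a median of 0.04 and a mean of −0.48 (adjusted p = 0.717). Housekeeping genes were 1 higher and 6 lower of 10 (−0.38; 0.0737) and germline genes 5 higher and 1 lower of 7 (0.52; 0.0792); both passed without wild-type 2iL replicate 2 (adjusted p = 0.046 for each).

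**Figure D2:**
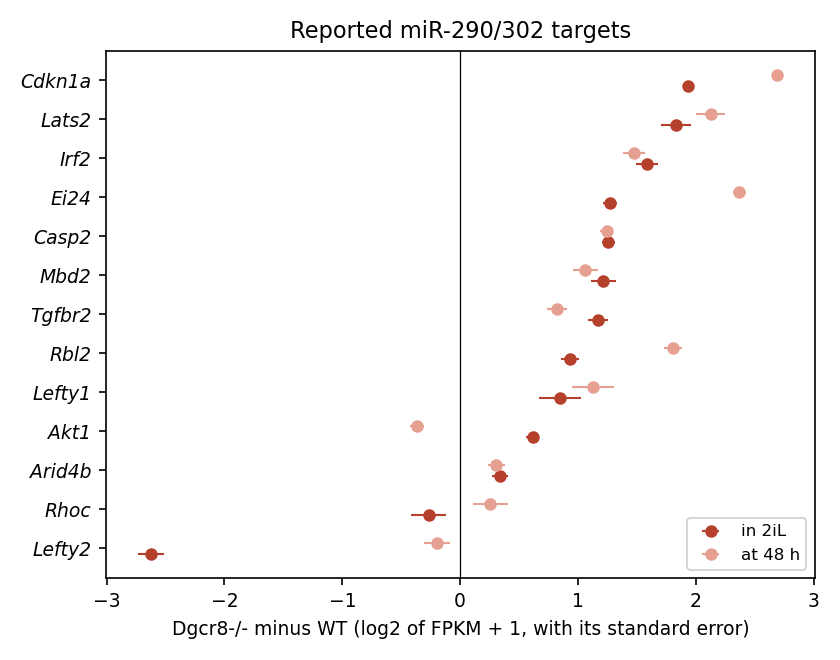
Log2 difference between knockout and wild type in 2iL and at 48 h for the 13 reported miR-290 and miR-302 targets, as points with standard errors from limma. Cdkn1a was higher by 1.93 in 2iL and 2.69 at 48 h, and Akt1 was higher in 2iL (0.61) and lower at 48 h (−0.36).

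At 48 h the genotypes were further apart, and now the naive genes separated them. Nanog stood at 56.4 FPKM in the knockout against 5.34 in wild-type cells, Esrrb at 49.6 against 4.85, Zfp42 at 116 against 20.4, Nr0b1 at 67.7 against 2.19 and Klf2 at 186 against 13.7. Sox2 was at 174 against 30.7 FPKM, and Pou5f1 at 847 against 716. Formative genes were lower, with Pim2 at 50.8 against 467.3, Dnmt3a at 62.2 against 274 and Pou3f1 at 14.7 against 55.3. Cdkn1a (142.7 against 21.2 FPKM) and Lats2 (12.3 against 2.06) remained higher.

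There were 9456 genes that differed at 48 h (4390 higher and 5066 lower in the knockout), 1488 higher and 1109 lower by at least 2-fold. Median-ratio scaling turned the split of all calls to 4752 higher and 4663 lower. The WNT antagonist Notum differed most among genes of ordinary length (168 against 0.913 FPKM; log2 6.47, SE 0.11, limma adjusted p = 5.1e-08). Other large differences were those of the autophagy receptor Calcoco2 (5.02), the membrane protein Emp1 (4.96) and Anxa2 (4.94). Lower genes were led by Car4 (0.169 and 0.588 FPKM against 40.1 and 36.9; log2 −4.86), Tmem54 (−4.79), the transcription factor Mef2b (−4.53), the tight-junction gene Cldn6 (−4.27), the myosin light chain Myl9 (−3.91) and Lin28a (−3.77).

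Of 18 naive genes, 16 were higher and 1 lower in the knockout at 48 h. The lower gene was Dppa3 (−0.40), a maternal factor that protects DNA from demethylation, and Gbx2 was not called (median 2.26, camera in limma, adjusted p = 2.0e-07, and adjusted p = 0.217 with an estimated correlation). Of the formative genes 13 were lower and 2 higher of 18, the latter being Otx2 (0.54) and Wnt8a (1.82), an inducer of mesoderm (−1.28, adjusted p = 0.0072, and adjusted p = 0.429 with an estimated correlation). Reported miR-290 and miR-302 targets were 10 higher of 13, with Ei24 at 2.37, Lats2 at 2.13 and Rbl2 at 1.80, and Akt1 was lower at −0.36 (1.13, adjusted p = 0.0042, and adjusted p = 0.232 with an estimated correlation). The p53 response was 10 higher and 2 lower of 13 (0.71, adjusted p = 0.0068, and adjusted p = 0.429 with an estimated correlation). The lower genes were the apoptotic Pmaip1 (−0.60) and the stress sensor Sesn2 (−0.14), whose small call was lost under some settings. G1/S regulators were 12 higher and 3 lower of 18 (0.66, adjusted p = 0.0206, and adjusted p = 0.280 with an estimated correlation). LIF/STAT3 genes were 8 higher and 1 lower of 11, with Il6st at 2.49 and the immediate-early gene Junb at −1.52 (0.48, adjusted p = 0.0268, and adjusted p = 0.280 with an estimated correlation). PI3K/AKT components were 10 higher and 2 lower of 17 (0.31, adjusted p = 0.0301, and adjusted p = 0.281 with an estimated correlation), with Akt1 among the lower genes. All 5 2-cell-like genes were higher (1.04, adjusted p = 0.0307, and adjusted p = 0.281 with an estimated correlation). Both of these calls ended with quantile scaling. Imprinted genes were 5 higher and 9 lower of 17 (−0.57; 0.291), with Meg3 (−2.76), Rian (−2.66) and Grb10 (−2.85) lower, and general pluripotency was 7 higher and 3 lower of 10 (0.26; 0.275). The difference between genotypes at 48 h went the same way as in 2iL for 6024 genes called in both conditions (2816 higher, against 1344 for independent lists, and 3208 lower, against 1660) and the opposite way for 726.

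Whether the change itself depended on the genotype was tested with the interaction, and many genes of naive pluripotency fell less in the knockout. The log2 change of Nanog was −5.07 in wild-type cells and −2.32 in the knockout, and the log2 changes were −4.87 and −1.86 for Esrrb, −3.14 and −0.36 for Klf2, and −4.04 and −0.30 for Nr0b1. The formative genes Pim2, Pou3f1, Dnmt3a and Fgf5 rose less, with Pim2 rising by 5.37 and 2.14. Dnmt3l and Otx2 went the other way: Dnmt3l fell slightly in wild-type cells (−0.44) and rose steeply in the knockout (4.16), and Otx2 rose more in the knockout (3.68 against 2.63).

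**Figure D3:**
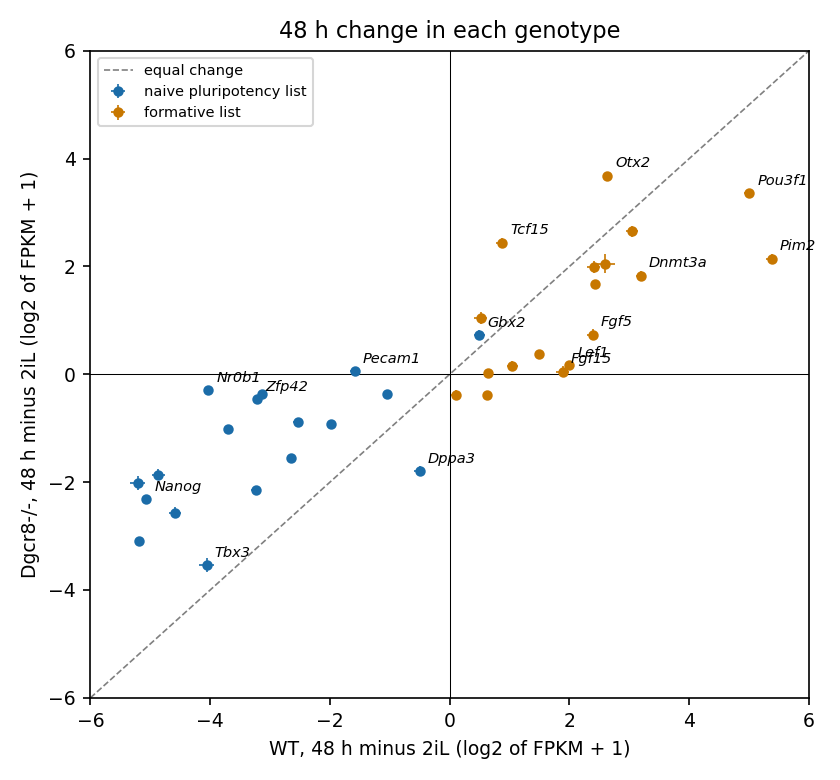
Log2 change by 48 h in wild-type cells (horizontal) and in knockout cells (vertical) for the naive genes in blue and the formative genes in orange, 1 point per gene with standard errors; the dashed line marks equal change. Most naive genes lie above the line, with a median difference of 1.84, and most formative genes below it, with a median of −0.81.

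The 48 h change differed for 5645 genes (2783 with a higher and 2862 with a lower value in the knockout), 828 and 821 of them by at least 2-fold. This near-even split turned with median-ratio scaling (2960 and 2923), a pseudocount of 0.1 (2741 and 2569) and a mean FPKM of at least 5 (2006 and 1608). It also turned without wild-type 2iL replicate 2 (2433 and 2393), wild-type 48 h replicate 1 (2287 and 2284) or knockout 2iL replicate 2 (2858 and 2485). Among the largest positive differences were those of Tgm1 (log2 5.08, SE 0.15, limma adjusted p = 1.7e-06), the thymic transcription factor Aire (4.72), Dnmt3l (SE 0.09, adjusted p = 6.2e-07) and the calcium-binding Efhd1 (4.51). Tgm1 fell from 21.9 to 1.54 FPKM in wild-type cells and went from 1.10 to 6.86 in the knockout. Car4 (−4.86), Tmem54 (−4.74) and Myl9 (−3.87) were the largest negative differences outside of paralogous genes, and each rose in wild-type cells. Snora34, Snora31, H2-Bl, Tmem181a and Tmem181b-ps also ranked high, but the first 2 are very short and the others have close paralogs. Across all genes the changes in the 2 genotypes were correlated (r = 0.456), with a slope of 0.373 for knockout on wild type. The same direction was called in both for 3455 genes (1900 rises, against 1080 for independent lists, and 1555 falls, against 736), and opposite directions for 875. The opposite genes include Akt1, which rose in wild-type cells (0.65) and fell in the knockout (−0.33), and Rbl2, which fell (−0.56) and rose (0.31). The knockout call of Rbl2 ended without 48 h replicate 1 (adjusted p = 0.059) or replicate 2 (adjusted p = 0.055).

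For naive pluripotency, 15 of 18 genes had a positive interaction (16 when adjusted over the list alone) and Dppa3 a negative one (−1.30). Tbx3 and Gbx2 were not called (median 1.84, camera in limma, adjusted p = 2.7e-10, and adjusted p = 0.121 with an estimated correlation). Formative genes gave 12 negative (14 when adjusted over the list alone) and 3 positive of 18, the positive ones being Otx2, Wnt8a and Tcf15, a marker of cells primed to differentiate (−0.81, adjusted p = 4.4e-04, and adjusted p = 0.331 with an estimated correlation). General pluripotency gave 6 positive (7 when adjusted over the list alone) and 0 negative of 10, with Sox2 at 1.53 (0.65, adjusted p = 0.0031, and adjusted p = 0.334 with an estimated correlation). LIF/STAT3 genes gave 7 positive and 1 negative of 11, the latter Pim1 at −0.43, a survival kinase (0.62, adjusted p = 0.0158, and adjusted p = 0.331 with an estimated correlation). Klf4, Klf5, Tfcp2l1 and Gbx2 of this list are counted in the naive list as well. WNT/beta-catenin genes gave 8 negative and 1 positive of 10, the positive being Notum at 4.33 (−0.89, adjusted p = 0.0061, and adjusted p = 0.331 with an estimated correlation). Germline genes gave 6 negative of 7, with Sycp3 (−1.65) and Ddx4 (−1.22), and 1 positive, the meiotic chromosome gene Hormad1 at 0.89 (−1.21, adjusted p = 0.0188, and adjusted p = 0.331 with an estimated correlation). All 5 2-cell-like genes were negative (−0.86, adjusted p = 0.0188, and adjusted p = 0.331 with an estimated correlation). The p53 response was just short of a call, with 9 positive and 3 negative of 13 (0.33, adjusted p = 0.0533), and passed without knockout 2iL replicate 1 (adjusted p = 0.043) and in several other settings. Reported miR-290 and miR-302 targets gave 4 positive and 1 negative of 13 (0.28; 0.233); Casp2 and Lats2 had interactions of −0.01 (adjusted p = 0.912) and 0.29 (adjusted p = 0.227).

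In the small RNA of wild-type cells, the miR-290 cluster was the most abundant family at every time, although its share fell by 48 h. That share of the summed signal was 40.1% at 0 h (SD 0.09), 41.2% at 12 h, 36.6% at 24 h and 27.9% at 48 h (SD 0.762). The level depended on what was summed, and went from 32.8% to 23.2% without the most abundant arm and from 45.1% to 33.1% with hairpin copies merged. The miR-302 cluster stood at 2.10%, 1.62%, 2.35% and 8.37% (SD 0.641 at 48 h), and the miR-106a cluster at 1.64%, 1.01%, 1.80% and 4.09%. Family shares sum all measured arms of the hairpins, whatever their seed. They are therefore not amounts of miRNA with a shared seed. miRNAs of the Sfmbt2 locus went from 6.04% to 14.6%, and let-7 from 0.247% to 0.0616%. These are shares of a fixed total, so a rise of one family lowers the others.

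**Figure D4:**
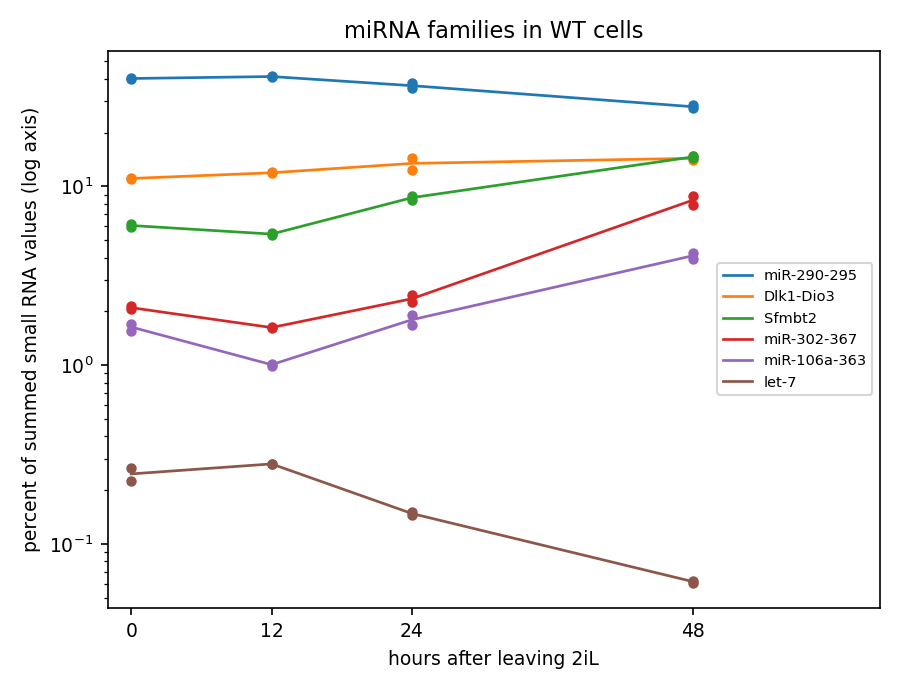
Percent of the summed small RNA signal on a log axis against hours after leaving 2iL for 6 families in wild-type cells; lines join the means of 2 libraries and points are libraries. The miR-302 share went from 2.10% at 0 h to 8.37% at 48 h, and the let-7 share from 0.247% to 0.0616%.

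By 48 h, 617 of 1415 arms changed by limma (333 rose, 284 fell), 225 rises and 159 falls of at least 2-fold; edgeR called 618 of 896, and 562 arms were called by both. With hairpin copies merged, 231 rose and 253 fell, so rises no longer prevailed. All 9 arms of miR-302 rose, with mir-302b-3p from 1326 to 4841 units (log2 1.87, SE 0.13, limma adjusted p = 8.7e-07; family median 2.08, camera adjusted p = 8.3e-07, and adjusted p = 0.176 with an estimated correlation). All 8 arms of miR-106a rose (1.57, adjusted p = 5.7e-05, and adjusted p = 0.176 with an estimated correlation). So did all arms of the Sfmbt2 locus but 2 that fell and 14 that were not called (1.16, adjusted p = 1.3e-34, and adjusted p = 0.176 with an estimated correlation). Many Sfmbt2 arms are copies of one another, and with copies merged the share of this locus went from 1.83% to 4.50%. Copies also enter the counts of other families at each time. The 22 let-7 arms hold 17 distinct mature arms, the 19 neural arms 9 and the 9 muscle arms 6. Counts and camera tests of such families therefore include members that are not independent. Of the miR-290 arms 12 of 14 fell (−0.68, adjusted p = 1.5e-04, and adjusted p = 0.283 with an estimated correlation), with mir-292-5p from 12060 to 6690 units; its call was lost with quantile scaling. let-7 gave 10 falls and 2 rises of 22, with let-7g-5p from 98.4 to 16.4 (−2.58, SE 0.11, limma adjusted p = 4.8e-08; family median −1.29, camera adjusted p = 3.0e-04, and adjusted p = 0.227 with an estimated correlation). The miR-182 arms fell, 6 of 6 (−0.78, adjusted p = 0.0023, and adjusted p = 0.176 with an estimated correlation). Epithelial miR-200 arms rose, 8 of 9 (0.80, adjusted p = 0.0047, and adjusted p = 0.176 with an estimated correlation).

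Among the remaining families, some were called at 48 h and others were not. Muscle miRNAs rose, 7 of 9, with mir-1a-2-3p from 0.444 to 14.9 units (family median 4.49, camera in limma, adjusted p = 0.0014, and adjusted p = 0.176 with an estimated correlation), though their share at 48 h was only 0.0302%. In the miR-34 family 4 of 6 rose, all from the miR-34b and miR-34c hairpins, while the abundant mir-34a-5p stood at 45.0 and 40.0 units and was not called (3.28, adjusted p = 0.0111, and adjusted p = 0.227 with an estimated correlation). Mesenchymal and feeder miRNAs gave 12 falls and 2 rises of 18, or 3 rises when adjusted over the list alone; mir-125b-1-3p fell by 4.43 log2 and mir-21a-5p, abundant in many differentiated cells, rose by 1.84 (−0.86, adjusted p = 0.0020, and adjusted p = 0.178 with an estimated correlation). Dlk1–Dio3 miRNAs gave 33 rises (35 when adjusted over the list alone) and 11 falls of 84 (0.29, adjusted p = 0.0401, and adjusted p = 0.227 with an estimated correlation), and quantile scaling ended this call. Not called were miR-17 (6 rises of 16; 0.25; 0.0946), miR-106b (2 falls of 6, 3 when adjusted over the list alone; −0.32; 0.0681), miR-15 and miR-16 (1 rise and 6 falls of 12; −0.44; 0.101), and miR-130 and miR-301 (4 falls of 8; −0.57; 0.0534). Nor were miR-181 (1 rise and 5 falls of 11, 3 and 6 when adjusted over the list alone; −0.73; 0.0796) and the neural miRNAs (8 rises and 9 falls of 19; median 0.00 and mean −0.31; 0.213). The miR-106b test passed without 48 h replicate 2 (adjusted p = 0.021), and the miR-181 test without 0 h replicate 2 (adjusted p = 0.036). Of single arms, mir-375-3p (0.193 to 12.5 units; log2 5.94, SE 0.20, limma adjusted p = 1.1e-08) rose most among those well above 0 throughout. The arms mir-670-3p (0.01 to 1.83), mir-1298-5p (0.0194 to 2.37), mir-384-5p and mir-670-5p (both 0 at 0 h; 0.604 and 0.501 at 48 h) appeared from almost nothing. The largest falls were those of mir-211-5p (38.7 to 1.00; −5.26), mir-211-3p (0.462 to 0), mir-125b-1-3p, mir-615-3p (−4.07) and mir-196a-1-3p (−3.95).

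At 12 h few arms had changed. The largest rises, at very low levels, were those of mir-670-5p (log2 3.77) and mir-670-3p (3.76), which rose further by 48 h. A pseudocount 10 times larger reduced them to 1.18 and 1.54, and the call of mir-670-3p ended without 12 h replicate 2 (adjusted p = 0.062). The miR-302 and miR-106a clusters were lower than at 0 h, and mir-21a-5p was already higher, at 3256 against 710 units (SE of the log2 change 0.10, limma adjusted p = 1.5e-06). mir-122-5p, the main miRNA of liver, went from 1.95 to 15.5 units at 12 h (2.98, SE 0.15, adjusted p = 1.8e-06) and back to 4.72 and 1.35 at 24 and 48 h. The neuronal-activity miRNAs mir-212-3p (0.0845 to 1.15 units) and mir-212-5p (0.259 to 2.19) rose too. In all, 42 arms rose and 82 fell (20 and 17 of them by at least 2-fold), but the total fell to 12 and 11 without 12 h replicate 1 or 2, and to 79 without 0 h replicate 2. The total also fell without either 48 h library, although these are not part of the contrast. Rises made up 33.9% of the calls by limma, 38.8% with median-ratio scaling, 46.3% with quantile scaling and 54.1% by edgeR, which called 185 arms. So neither scaling alone turned the direction that prevailed. The edgeR fit differed in test, filter and scaling at once. Rises also prevailed in some fits without 1 library.

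Of the families at 12 h, miR-106a had 6 falls of 8 (median −0.66, camera in limma, adjusted p = 1.3e-05, and adjusted p = 0.176 with an estimated correlation). The miR-302 cluster had 5 falls of 9, 7 when adjusted over the list alone (−0.41, adjusted p = 2.6e-04, and adjusted p = 0.178 with an estimated correlation). Sfmbt2 miRNAs had 15 falls and no rise (−0.14, adjusted p = 9.2e-05, and adjusted p = 0.340 with an estimated correlation). Dlk1–Dio3 miRNAs had 2 rises of 84, none when adjusted over the list alone (0.11, adjusted p = 0.0010, and adjusted p = 0.176 with an estimated correlation). The other 12 h calls each ended when some single library was left out. They were miR-181 (2 falls of 11, 5 when adjusted over the list alone; −0.52, adjusted p = 0.0074, and adjusted p = 0.227 with an estimated correlation; 0.14 without 0 h replicate 1) and neural miRNAs (7 rises of 19, or 8 with 3 falls when adjusted over the list alone; 0.11, adjusted p = 0.0111, and adjusted p = 0.178 with an estimated correlation; 0.055 without 0 h replicate 2). Muscle miRNAs did so too (no arm called; 0.61, adjusted p = 0.0124, and adjusted p = 0.178 with an estimated correlation; 0.072 without 0 h replicate 2). The same held for let-7 (no arm called; 0.31, adjusted p = 0.0282, and adjusted p = 0.328 with an estimated correlation; 0.42 without 0 h replicate 2) and miR-200 (1 fall of 9; −0.25, adjusted p = 0.0408, and adjusted p = 0.227 with an estimated correlation; 0.087 without 0 h replicate 2). The miR-290 family had no called arm at 12 h (median 0.00 and mean 0.01, adjusted p = 0.705).

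By 24 h the 48 h pattern had begun. Of 362 called arms, 207 rose and 155 fell, 48 in each direction by at least 2-fold, and edgeR called 428. Rises made up 57.2% of the calls, but 49.1% with hairpin copies merged. mir-375-3p had reached 10.1 units and mir-1a-2-3p 4.97, while let-7g-5p had fallen to 52.3 and mir-181d-5p from 197 to 99.6. Sfmbt2 miRNAs gave 85 rises and 58 uncalled arms, or 102 rises and 1 fall when adjusted over the list alone (median 0.46, camera in limma, adjusted p = 2.6e-20, and adjusted p = 0.178 with an estimated correlation). Muscle miRNAs had 6 rises of 9 (2.88, adjusted p = 1.6e-04, and adjusted p = 0.176 with an estimated correlation). The let-7 family had 9 falls of 22 (−0.56, adjusted p = 8.4e-04, and adjusted p = 0.227 with an estimated correlation). The calls of miR-290 (4 falls of 14, 5 when adjusted over the list alone; −0.18, adjusted p = 0.0282, and adjusted p = 0.421 with an estimated correlation), miR-106a (3 rises of 8, or 7 with 1 fall when adjusted over the list alone; 0.36, adjusted p = 0.0282, and adjusted p = 0.283 with an estimated correlation) and miR-181 (4 falls of 11; −0.13, adjusted p = 0.0282, and adjusted p = 0.283 with an estimated correlation) were less stable. They ended without 24 h replicate 1 (0.12), 24 h replicate 2 (0.071) and 0 h replicate 1 (0.18), in that order. miR-302 was not called at this time (3 rises and 1 fall of 9; 0.21; 0.0907). Over the whole course, the moderated F test in limma called 640 arms and the edgeR test 692.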

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

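All tests of explanations in this part were chosen after the result was seen, except the first blood test and the liver test for mir-122-5p. The first results listed are those where the 48 h change differed between the genotypes by the interaction test in limma. The 2 patterns of the last 2 paragraphs were picked outside that rule, after their values were seen. A called interaction held for 5645 genes, and 875 genes changed in opposite directions, beside 3455 called in the same direction. The number of opposite genes for independent lists was not computed, so 875 is not a sign of an excess. Lists whose interaction was called had medians of 1.84 (naive pluripotency), 0.65 (general pluripotency), −0.81 (formative and primed), −0.89 (WNT/beta-catenin response), 0.62 (LIF/STAT3 response), −1.21 (germline genes) and −0.86 (2-cell-like genes). None of these list calls held with an estimated correlation (adjusted p = 0.121 to 0.334). Of the 18 genes named in every comparison, 15 had a called interaction. Among them, Akt1 (−0.98), Dgcr8 (−0.36) and Rbl2 (0.87) changed in opposite directions in the 2 genotypes. The call within the knockout ended when a single library was left out for Rbl2, and the calls within both genotypes did so for Dgcr8, so these 2 reversals are less certain.

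Naive genes fell less in the knockout. A loss of miRNA control over the exit from 2iL is the biological explanation that the design offers, and it was not tested here. Another explanation is that the knockout cultures at 48 h still held undifferentiated cells, which a loss of that control could itself leave behind. By 2 SD, 13 of 15 naive genes with a called positive interaction kept more of their 2iL level than a mixture would allow. The mixture was of cells at the 2iL level and cells with the wild-type 48 h share. Its part at the 2iL level was set to the lowest share kept by any of these 15 genes, so the bound came from the data it tested. The share kept ran from 10.8% for Tfcp2l1 to 104% for Pecam1. Both profiles came from measured groups, but whether cells in the knockout 48 h cultures had them was assumed and not measured. This explanation therefore cannot be told apart from the others. Scaling does not account for it, since the lowest median interaction with other scalings was 1.73. A smaller response of all genes was not excluded. The naive median in the knockout, −1.28, lay inside the range of −1.46 to −0.20 of random lists matched on the wild-type change. It lay near the lower end, at percentile 5.93, and the random median was −0.65, so the naive genes fell further than most such lists. The changes in the 2 genotypes were correlated only at 0.456. Genes picked for a large wild-type change would therefore change less in the knockout even without a general damping. The test cannot tell these 2 apart. With 1 line per genotype another difference between the lines cannot be excluded.

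Meg3, Rian and Mirg, which carry the miRNAs of the Dlk1–Dio3 locus, were lower in the knockout in 2iL (log2 −3.09, −2.97 and −1.87). If the knockout changed all miRNA host transcripts in one way, the others should be lower too, but 3 of the other 6 were called higher and 0 lower, which argues against this. A change of imprinting or of the locus in the knockout line could give the same values, and with 1 line per genotype it cannot be told apart from an effect of Dgcr8.

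mir-122-5p peaked at 12 h, and the design gives no biological explanation for it, so none was tested. RNA from blood in the 12 h cultures would raise blood miRNAs, and the summed level of 12 of them changed by −10.9 (SD 18.3) from 222 to 211 units; this test, fixed beforehand, was undecided, because its spread exceeds the rise of 13.5 in mir-122-5p. A later test on the 9 blood miRNAs of low level gave −0.10 (SD 0.513), below the rise by more than 2 SD, which would count against blood. Only 2 of the 9 reached 10 reads in every 0 h and 12 h library, but a low start does not hide a rise. The 9 summed to 3.60 units at 0 h and 3.50 at 12 h. These values argue against blood RNA that carries the 9 at least as strongly as mir-122-5p. Blood RNA with less of them cannot be told apart. RNA from liver cannot be excluded as a whole, because how strongly liver carries its other miRNAs beside mir-122-5p, the main one, was not measured. Here 3 of 3 liver miRNAs with low starting levels were not called higher, which met the bound fixed beforehand for excluding it. That bound was set aside after the result was seen, because only 1 of the 3 reached 10 reads in every library. As for blood, a low start does not hide a rise. By 12 h the 3 went from 4.76 to 4.04, 0.283 to 0.24 and 0 to 0.0152 units, against the rise of 13.5. These values argue against liver RNA that carries the 3 at least as strongly as mir-122-5p. Liver RNA with less of them cannot be told apart.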

How the results depend on the processing

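The tests with edgeR, merged hairpin copies and median-ratio scaling of named genes, named miRNAs and families were chosen after the result was seen, as were some further settings for miRNAs and families. Counts of changed genes kept within 1.5 times their values in most settings. Over all alternatives they ran from 4983 to 8148 in wild-type cells, 4312 to 6769 in the knockout, 5954 to 8659 between genotypes in 2iL, 6515 to 10698 at 48 h and 3614 to 5956 for the interaction. The lowest counts came with a mean FPKM of at least 5, which tests fewer genes. Those ranges leave out the setting that also required a log2 change of at least 1, which by construction left 1832, 1210, 1579, 2597 and 1649 genes in that order. Called arms ran from 250 to 428 at 24 h and 484 to 634 at 48 h.

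No gene list stayed called with an estimated correlation in any of the 5 comparisons (0 in each), and no miRNA family did (0 of 26). The preset correlation of 0.01 makes only a small, fixed allowance for shared variation, and with 2 libraries per group an estimate is itself imprecise. Restricting families to the 708 most abundant arms left 15 called. Most family shares moved when the most abundant arm was left out or hairpin copies were merged, and 11 kept their values. Called arms at 12 h ranged from 11 to 1.4e+02 (rounded) when single libraries were left out. Fits without 1 library have fewer samples; the cause was not tested further.

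Reversals of sign occurred only for named results that were not called in the fit reported, and the cause was not tested. The Casp2 interaction was 0.0107 with quantile scaling and −0.0589 to 0.0326 without single libraries. At 12 h, mir-92a-1-3p was 0.0420 with quantile scaling, 0.0616 by edgeR and −0.0518 to 0.0070 without single libraries. mir-16-2-5p was 0.0820 and 0.0671 by the same methods and −0.133 to 0.0976 without single libraries. mir-127-3p was −0.0479 with quantile scaling and −0.0431 to 0.0568 without single libraries, and let-7g-5p was −0.0575 to 0.240 without them. At 24 h, mir-302b-3p was −0.0477 with quantile scaling and −0.0797 to 0.187 without single libraries. mir-25-3p was −0.0166 with median-ratio scaling, −0.0080 by edgeR and −0.0866 to 0.116 without single libraries. mir-130b-5p was −0.0902 with quantile scaling, and mir-128-1-3p was −0.0726 with quantile scaling and −0.0513 to 0.192 without single libraries. In all, 40 of 479 results for named genes and 16 of 80 for named miRNAs lost a call in some setting.

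A term for the replicate number (a block, as if replicates were paired) gave 7222, 6100, 8192, 9321 and 5365 genes for the 5 comparisons, and for small RNA 366 arms at 24 h, 608 at 48 h and 29 families against 26. The differences between replicates were correlated across groups at −0.153 to 0.18 for total RNA and −0.276 to 0.263 for small RNA. The planned tests of miRNA seed sites were not run, because no 3′ untranslated-region sequences were available. Depth limits small RNA at low levels, where 3 reads correspond to 0.0361 to 0.0607 units; read numbers of the total RNA libraries are unknown.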

Other observations

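The tests in this part were the limma comparisons fixed beforehand, and the genes below were picked after the result was seen. The demethylase gene Tet2 went from 10.3 to 0.944 FPKM in wild-type cells and from 19.6 to 10.2 in the knockout, and Tet1 from 42.3 to 26.8 and from 42.9 to 56.7. Both interactions were called (log2 1.65 for Tet2 and 1.03 for Tet1; adjusted p = 3.7e-05 and 2.2e-04). The receptor subunit Il6st, which carries the LIF signal, was higher in the knockout in 2iL (61.9 against 16.2 FPKM) and at 48 h (35.7 against 5.57).

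Genes of the mitochondrial genome held 1.36% to 1.70% of the summed FPKM in wild-type libraries and 2.02% to 2.27% in knockout libraries.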
